A study of Rattus norvegicus with 6 samples.

How the data were processed

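Expression was measured in 6 arrays of TGF-β1-treated NRK-52E cells, 3 with an AMPKα2 shRNA lentivirus and 3 with a control lentivirus. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared from 10 µg of it with a one-cycle Affymetrix kit. The values were deposited by the authors as log2 expression, 1 value per probe set and array. How the authors corrected the background, summarised probes and normalized the arrays is not given in the sources used here. The deposited values ranged from 2.37 to 13.84 without missing entries. The means per array were nearly equal, from 6.16 to 6.19, while the quartiles differed between the groups, so the distributions had not been made identical. Signal over background was not given for each probe set.

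Of 31099 probe sets, 57 were array controls and were left out of all gene tests. Of the other 31042, 20826 were paired with 1 gene in the platform annotation, 436 with several and 9780 with none, and those with several or none were used only at the level of probe sets. The RefSeq gene table of assembly GRCr8 was used for names only, through Entrez identifiers. It matched 20758 probe sets and changed 0 symbols. For each of 14217 genes the probe set with the highest mean over the 6 arrays was used. Of 4525 genes with more than 1 probe set, 928 (20.5%) had probe sets that passed in opposite directions.

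The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), on the deposited values with no further normalization, no filter on level and no covariate, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are AMPKα2 shRNA minus control on the log2 scale. Gene lists were 41 sets written before the data were examined, covering AMPK signalling, epithelial and mesenchymal genes, matrix, TGF-β, cytoskeleton, metabolism, proliferation, stress, immune response, signalling pathways and markers of other kidney cell types. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and limma's fry. The genes named were also fixed before the data were examined. They are all measured AMPK subunits and Cdh1, Vim, Fn1, Acta2, Col1a1, Snai1, Tgfb1 and Ccn2, whether or not they passed. A further gene of that rule is not reported here. To these come the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and whose mean in the higher group was above the median level, without provisional symbols. From each list described, up to 2 rising and 2 falling genes with the largest change among those that passed may be named. With 3 arrays against 3, an exact permutation test of a single value cannot give a 2-sided p under 0.1.

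Alternatives fixed before the data were examined were quantile normalization, median centring, removal of the lowest 25% or 50% of genes by mean level, the mean or the most variable probe set per gene, an intensity trend or robust variance in eBayes, array weights, the replicate number as a block, a floor of 4, leaving out each array, other thresholds and the other set tests. Cyclic loess in 3 iterations was added after the narrower range of values on the AMPKα2 shRNA arrays had been seen. Random lists matched on level were drawn 10000 times.

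The steps were tested on simulated arrays made from the real means and spreads of 14217 genes, with 200 genes changed. Each simulated gene had the same spread in both groups. On the real arrays the median SD of a gene was 0.132 with the AMPKα2 hairpin and 0.072 with the control, a difference that the simulation left out. For the count of genes changed, 93% of 2-fold and 56% of smaller (log2 of 0.5) changes were recovered, and 6 unchanged genes passed. When the simulated AMPKα2 shRNA arrays were narrowed linearly about the mean by 0.803, the ratio of SDs in the deposited values, 9348 unchanged genes passed without normalization. After quantile normalization 2 passed, and after cyclic loess 3. Both scalings undo a linear narrowing, while the deposited change was not linear in level. Its median was 0.81 at control levels of 5 to 6 but 0.52 under 4, and -0.90 at 9 to 10 but -0.27 above 12. The small counts thus do not show how many unchanged genes pass on the real arrays. For the gene lists, a shift of the mitosis list was recovered and 0 of the other lists passed. That test kept the range and drew the noise of each gene independently. It therefore does not show how often lists pass by error with narrowed arrays or correlated genes.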

Results

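Gene expression was measured in NRK-52E cells, an established line of rat kidney tubule epithelium, on 6 Affymetrix rat arrays. All cells had received TGF-β1, a cytokine used to drive epithelial cells towards a mesenchymal state, at 10 ng/mL for 24 h. The cells of 3 arrays carried a lentivirus with a short hairpin RNA against AMPKα2, a catalytic subunit of the energy sensor AMP-activated protein kinase, and those of 3 arrays carried a control lentivirus. The labels call the 3 arrays of each group biological replicates. The design asks which transcripts differ once AMPKα2 is targeted in cells under TGF-β1, and no cells without TGF-β1 were analysed here. Deposited log2 values of 31042 probe sets had medians of 6.04, 6.04 and 6.05 on the AMPKα2 shRNA arrays and 5.83, 5.82 and 5.82 on the control arrays. Their SD over probe sets was 1.82, 1.81 and 1.76 on the AMPKα2 shRNA arrays and 2.17, 2.18 and 2.19 on the control arrays. The number of arrays limits the precision of every value.

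Prkaa2, which encodes the targeted AMPKα2, was read by 1 probe set. It stood at 6.63 ± 0.14 (SD, n = 3) on the AMPKα2 shRNA arrays and 6.84 ± 0.05 on the control arrays. Its log2 fold change of -0.21 (SE 0.09) did not pass the test (limma, adjusted p = 0.0552). Each AMPKα2 shRNA array lay below each control array, but the groups did not overlap in 87.1% of all genes. Changes of -0.05 after quantile normalization and -0.15 after cyclic loess did not pass either, while -0.42 after median centring passed. A knockdown of AMPKα2 was thus not shown by the values as deposited, and groups are named as the labels name them. The hairpin's sequence was not used here, so which transcripts it targets was not checked. Prkaa1, which encodes the other catalytic subunit, AMPKα1, fell by 2.34 on the log2 scale (SE 0.09, limma, adjusted p = 7.04e-09). Its other probe sets gave -1.03 at a control level of 7.41 and 0.55 at a low control level of 3.87. Genes with a control level under 4 had a median change of 0.52. The probe sets of Prkaa1 thus did not share a direction, the one that rose was at a low level, and their mean changed by -0.94. Of 7 measured subunit genes, 2 rose, 3 fell and 2 did not pass. Prkab2 rose by 0.95 (0.58 after cyclic loess) and Prkag3 by 0.52 with the values as deposited, and the changes of Prkag3 after quantile normalization (0.20) and cyclic loess (0.01) did not pass. Prkab1 and Prkag1 had log2 fold changes of -0.24 and -0.29, which turned to 0.50 and 0.47 after quantile normalization and to 0.47 and 0.42 after cyclic loess, and were -0.46 and -0.50 after median centring. Without control replicate 2 the change of Prkab1, -0.20, did not pass. Prkag2 had a log2 fold change of -0.18 that did not pass, a change of -0.40 after median centring and a mean over probe sets of 0.23, both of which passed, and its other probe sets passed in both directions, at -0.39, 0.63 and 0.85. The subunit list as a whole did not pass the set test (camera, adjusted p = 0.715).

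The groups differed in most genes. Of 14217 genes, 12095 passed an adjusted p of 0.05 in limma, 6199 higher and 5896 lower with the AMPKα2 hairpin. At least a 2-fold change was seen in 4293 of them, 1654 higher and 2639 lower. Among all genes, 12378 (87.1%) had groups that did not overlap, where chance gives 10%. At the level of single probe sets, 25419 of 31042 passed, 14848 higher and 10571 lower. The direction of change followed the expression level. The median log2 fold change was 0.79 among 1983 genes with a control level between 4 and 5, and -0.90 among 1602 genes between 9 and 10. Spiked controls moved as well. The 14 probe sets for bioB, bioC and bioD, added at hybridisation, were lower on all AMPKα2 shRNA arrays, with a mean change of -0.88. The 4 probe sets for cre, another hybridisation spike, lay near the top of the range, at control levels of 12.52 to 13.45, and had a mean change of 0.11, and 24 probe sets for the spikes dap, lys, phe and thr had -1.21. After quantile normalization 10337 genes passed (6225 higher, 4112 lower), and after cyclic loess 10206 (5722 higher, 4484 lower). The median change over all genes was 0.05 as deposited, 0.16 after quantile normalization, 0.09 after cyclic loess and -0.17 after median centring. The split of 2-fold changes moved with the scaling, to 1525 higher and 1470 lower after quantile normalization, 1085 and 1546 after cyclic loess, and 642 and 3505 after median centring. In all 4 scalings, 7387 genes passed in 1 direction, 3628 higher and 3759 lower, and 1665 of them changed at least 2-fold in each, 321 higher and 1344 lower.

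**Figure D1:**
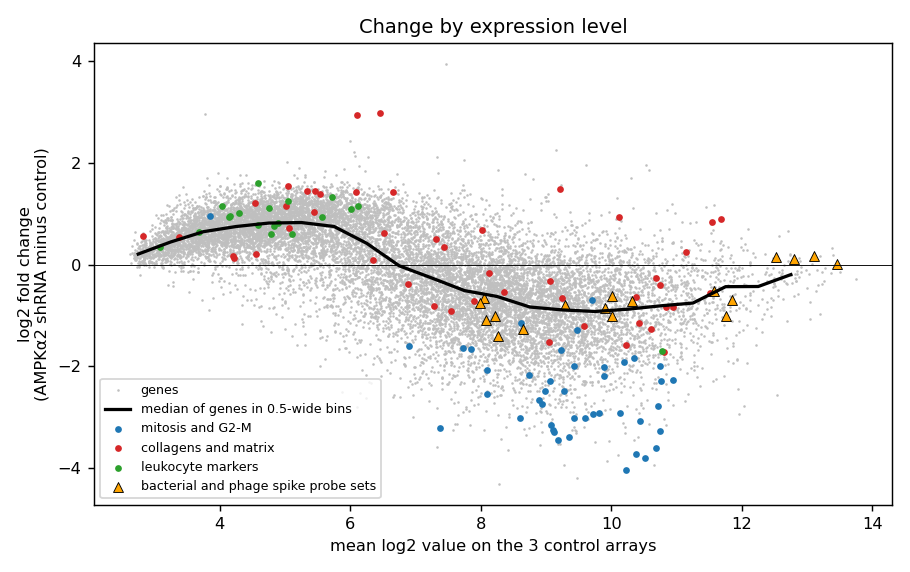
Log2 fold change (AMPKα2 shRNA minus control) against the mean log2 value on the 3 control arrays, 1 point per gene, with the median of genes in bins 0.5 wide as a line, 3 gene lists in colour and hybridisation spike probe sets as triangles. Genes at control levels of 4 to 5 had a median of 0.79 and genes at 9 to 10 a median of -0.90, and most genes of the mitosis list lay far below the line.

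Genes of cell division were lower with the AMPKα2 hairpin. Of 43 measured genes of mitosis and the G2-M phases, 42 fell and 1 rose, with a median log2 fold change of -2.54, and the list passed the set test (camera, adjusted p = 4.39e-14). With an estimated correlation it passed at adjusted p = 0.0474. Ccna2, which encodes cyclin A2, fell by 4.04 (SE 0.08), from 10.22 ± 0.09 (SD, n = 3) to 6.17 ± 0.06. Racgap1, a regulator of cytokinesis, fell by 3.81 (SE 0.13), and the proliferation marker Mki67 fell by 3.73 (SE 0.11). Cdc25b, a phosphatase that activates mitotic kinases, was the member that rose, by 0.95 (SE 0.14) from a low level of 3.85, and by 0.50 after quantile normalization and 0.45 after cyclic loess. Of 39 genes of DNA replication and the S phase, 37 fell and 0 rose, with a median of -1.50 (camera, adjusted p = 4.89e-10). That list gave adjusted p = 0.195 with an estimated correlation, and passed with one after quantile normalization (adjusted p = 0.0253) and cyclic loess (adjusted p = 0.0289). Uhrf1, which helps maintain DNA methylation, fell by 3.09 (SE 0.12) and Mcm6, a part of the replicative helicase, fell by 2.73 (SE 0.08). After quantile normalization the medians were -2.15 for the mitosis list and -1.04 for the replication list, and after cyclic loess they were -2.06 and -1.04. All 4 scalings together kept 41 falling genes of the mitosis list and 34 of the replication list.

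Smooth muscle and matrix genes were among those with the largest rises. Tagln, which encodes the actin-binding protein transgelin, rose by 3.94 (SE 0.09), from 7.47 ± 0.04 (SD, n = 3) to 11.41 ± 0.12. Acta2, which encodes α-smooth muscle actin, rose by 1.48 (SE 0.09), and the fibronectin gene Fn1 rose by 1.97 (SE 0.08). The type I collagen genes Col1a1 and Col1a2 rose by 2.98 (SE 0.09) and 2.95 (SE 0.12), and Postn, which encodes the matrix protein periostin, rose by 2.12 (SE 0.08). Ccn2, a TGF-β-responsive matricellular gene, rose by 0.66 (SE 0.08), from 12.71 to 13.37. These 7 genes kept their rise in all 4 scalings, and the largest adjusted p among them as deposited was 1.27e-05 (limma). Other mesenchymal genes went the other way: S100a4 fell by 1.48, with -0.91 after quantile normalization and -0.87 after cyclic loess, and Wnt5a fell by 1.52. Vim, the vimentin gene, fell by 0.38, and by 0.59 after median centring, and its change of -0.15 after cyclic loess did not pass. Ccn2 and Vim, which stood at 13.22 on the control arrays, lay near the highest deposited value of 13.84, so the sizes of their changes are uncertain. Snai1, a repressor of E-cadherin, had a log2 fold change of -0.07 that did not pass, and passed in opposite directions after quantile normalization (0.21) and median centring (-0.29). The list of mesenchymal genes had 25 of 41 members higher, 11 lower and 5 that did not pass (camera, adjusted p = 0.0687). That list passed after median centring and without the lowest 25% or 50% of genes, and its adjusted p ranged from 0.000326 to 0.331 over all alternatives with the preset correlation. With an estimated correlation it did not pass as deposited (camera, adjusted p = 0.7445), after quantile normalization (0.5861) or after cyclic loess (0.4473). Of 47 collagen and matrix genes 22 rose, 19 fell and 6 did not pass (camera, adjusted p = 0.389). The laminin genes Lamc1 and Lamb2 had log2 fold changes of -1.72 and -1.58, which were -1.06 and -0.85 after quantile normalization and -1.05 and -0.87 after cyclic loess.

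Contractile genes moved in both directions. Of 33 genes of the actin cytoskeleton, 13 rose, 16 fell and 4 did not pass (camera, adjusted p = 0.777). The nonmuscle myosin heavy chain genes parted: Myh9 rose by 1.95 (SE 0.08) and Myh10 fell by 1.92 (SE 0.09), with -1.20 after quantile normalization and -1.19 after cyclic loess. Cnn2, which encodes calponin 2, fell by 2.25 (SE 0.08). The list's median of -0.03 turned to 0.12 after quantile normalization and to 0.01 after cyclic loess.

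Of 38 genes of the TGF-β pathway and its targets, 12 rose, 23 fell and 3 did not pass (camera, adjusted p = 0.143). Skil, which encodes a repressor of SMAD signalling, fell by 2.35 (SE 0.08), and the BMP receptor gene Bmpr1a fell by 1.91 (SE 0.08). Fst, which encodes the activin antagonist follistatin, rose by 1.71 (SE 0.08), and the co-receptor gene Tgfbr3 rose by 1.48 (SE 0.09). The other probe set of Tgfbr3 rose by 0.35, and the mean of its probe sets by 0.92. Tgfb1 itself had a log2 fold change of -0.29 (SE 0.09, limma, adjusted p = 0.0114), which was 0.06 after quantile normalization and -0.02 after cyclic loess, neither of which passed, and -0.50 after median centring. Without control replicate 2 the change of Tgfb1, -0.25, did not pass. The list's median of -0.59 was 0.02 after quantile normalization and -0.04 after cyclic loess.

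Of 38 epithelial junction and identity genes, 26 rose, 7 fell and 5 did not pass (camera, adjusted p = 0.0507). The list's median of 0.49 lay at percentile 69.8 of random lists of the same mean level, against a random median of 0.43. A rise beyond that of genes of its level was thus not shown for the list's median. The list passed after median centring, with array weights, without AMPKα2 shRNA replicate 2 and without control replicate 2. Its adjusted p ranged from 0.0383 to 0.965 over all alternatives with the preset correlation. With an estimated correlation it did not pass as deposited (camera, adjusted p = 0.7445), after quantile normalization (0.9204) or after cyclic loess (0.9802). The tight junction genes Tjp1 and F11r, which were highly expressed, had log2 fold changes of -1.86 (SE 0.08) and -1.79 (SE 0.08). The other probe set of Tjp1, at a control level of 5.21, had -0.33, and the mean of its probe sets changed by -1.09. The change of F11r was -1.08 after quantile normalization and -1.09 after cyclic loess. Cldn6 and Crb3, a claudin and a polarity gene at control levels of 4.35 and 5.23, rose by 1.20 (SE 0.14) and 1.19 (SE 0.13), and by 0.60 and 0.74 after cyclic loess. After quantile normalization Cldn6 rose by 0.77. Cdh1, the E-cadherin gene, had a log2 fold change of 0.43 (SE 0.12) at a control level of 4.31, which passed (limma, adjusted p = 0.00513). Its changes of -0.03 after quantile normalization, -0.11 after cyclic loess and 0.21 after median centring did not pass. The other probe set of Cdh1 had 0.02, which did not pass, and the mean of its probe sets rose by 0.23. The median over the list was 0.49 as deposited, 0.26 after quantile normalization and 0.20 after cyclic loess.

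**Figure D2:**
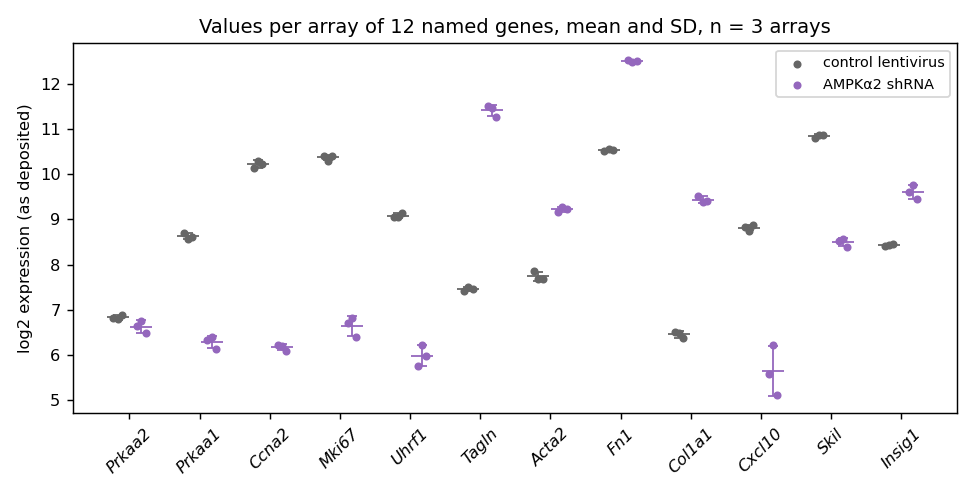
Deposited log2 values of 12 named genes on each array, with control lentivirus in grey and AMPKα2 shRNA in purple; horizontal marks are means and bars are SD over n = 3 arrays. The means of Tagln were 7.47 and 11.41, those of Ccna2 10.22 and 6.17, and those of the targeted gene Prkaa2 6.84 and 6.63.

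Inflammatory genes had no shared direction. Of 46 measured, 23 rose, 17 fell and 6 did not pass (camera, adjusted p = 0.502), with a median of 0.25 and a mean of -0.03. The chemokine genes Cxcl10 and Ccl2 had log2 fold changes of -3.17 (SE 0.21) and -2.42 (SE 0.09). Nos2, the inducible nitric oxide synthase gene, rose by 1.31 (SE 0.09), and the chemokine gene Cxcl3 rose by 1.23 (SE 0.09). Of the 5 probe sets of Cxcl3, 2 did not pass, at 0.06 and 0.15, and their mean rose by 0.58. Of 39 interferon response genes, 7 rose, 18 fell and 14 did not pass (camera, adjusted p = 0.102). The immunoproteasome gene Psmb9 fell by 2.77 (SE 0.10) and Sp110 fell by 1.90 (SE 0.10), while Ifit1 rose by 1.37 (SE 0.11). The mean of the probe sets of Sp110 changed by -1.23, and Ifit1 rose by 0.81 after cyclic loess. The interferon list passed the set test after quantile normalization, with a median of -0.23, and after cyclic loess, with a median of -0.34. With an estimated correlation it passed in neither (adjusted p = 0.234 and adjusted p = 0.194). It also passed after median centring, with a median of -0.39.

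Genes of the AMPK and mTOR signalling axis were split as well. Of 32 measured, 10 rose, 17 fell and 5 did not pass (camera, adjusted p = 0.493). Ppargc1a, which encodes a coactivator of mitochondrial genes, rose by 1.55 (SE 0.10), and the autophagy kinase gene Ulk1 rose by 1.41 (SE 0.09). The other probe sets of Ppargc1a gave 0.42 and 0.23, the second of which did not pass, and its rise was 0.73 with the mean of probe sets and 0.97 after cyclic loess. Sesn3, a sestrin gene, fell by 2.26 (SE 0.11), while its other probe set rose by 0.34 and the mean of its probe sets changed by -0.96. Map3k7, which encodes the kinase TAK1, had a log2 fold change of -1.50 (SE 0.08), and of -0.75 after quantile normalization and -0.77 after cyclic loess. The list's median was -0.22 as deposited, 0.23 after quantile normalization and 0.16 after cyclic loess. Of 36 fatty acid oxidation genes, 14 rose, 14 fell and 8 did not pass (camera, adjusted p = 0.943). Its median of 0.09 was 0.25 after quantile normalization, 0.16 after cyclic loess and -0.13 after median centring, and its mean as deposited was -0.17. Eci2 and Acsl4, which encode an enoyl-CoA isomerase and an acyl-CoA synthetase, had log2 fold changes of -2.06 and -1.97, and that of Acsl4 was -1.28 after quantile normalization and -1.26 after cyclic loess. Ppara rose by 1.13 from a control level of 5.01, and by 0.60 after cyclic loess. Acot2 rose by 0.94, and by 1.49 after both quantile normalization and cyclic loess. The other probe sets of Acot2, at 0.18 and 0.32, did not pass. Of 42 autophagy and lysosome genes, 12 rose, 11 fell and 19 did not pass (camera, adjusted p = 0.987). The median of that list was -0.01 as deposited and 0.57 after both quantile normalization and cyclic loess. It passed the set test after cyclic loess, with 30 genes higher and 11 lower, but not with an estimated correlation there (adjusted p = 0.233), and it passed without the lowest 50% of genes. Atg2a rose by 1.13 (SE 0.08) and Becn1, which encodes beclin 1, fell by 1.67 (SE 0.09). After quantile normalization they had 1.73 and -1.03, and after cyclic loess 1.77 and -1.01.

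Of 20 cholesterol synthesis genes, 10 rose, 4 fell and 6 did not pass, with a median of 0.19 (camera, adjusted p = 0.327). After quantile normalization 17 rose and 2 fell, with a median of 0.80, and after cyclic loess 16 rose and 2 fell, with a median of 0.76, and the list passed in both. It also passed without the lowest 50% of genes, with a median of 0.16. With an estimated correlation it passed in neither (adjusted p = 0.234 and adjusted p = 0.194). Insig1, a sterol-regulated gene of the endoplasmic reticulum, rose by 1.17 (SE 0.09) and Acat2 fell by 1.31 (SE 0.09). After quantile normalization they had 1.85 and -0.66, and after cyclic loess 1.90 and -0.67. Srebf2, which encodes the transcription factor of the pathway, fell by 0.56 as deposited and had 0.20 after quantile normalization, which passed, and 0.17 after cyclic loess, which did not. Its other probe set rose by 0.52, and the mean of its probe sets, at -0.02, did not pass. Of 24 p53 target genes, 7 rose, 12 fell and 5 did not pass (camera, adjusted p = 0.258). Ccng1 and Epha2, a cyclin G and an ephrin receptor gene, had log2 fold changes of -2.93 (SE 0.09) and -2.25 (SE 0.08). Perp and Sesn1 rose by 0.94 and 0.67 from low control levels of 4.28 and 4.92, and neither passed after cyclic loess. The other probe set of Sesn1 had -0.66.

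Markers of cell types other than tubule epithelium were mostly expressed at low levels and were higher on the AMPKα2 shRNA arrays. So were most genes of such levels: 89.9% of all genes at control levels of 4 to 5 and 80.8% at 5 to 6 passed as higher. Of 19 leukocyte markers 18 rose and 1 fell, with a median of 0.94 (camera, adjusted p = 0.00101). Of 16 endothelial markers 15 rose, with a median of 0.78 (camera, adjusted p = 0.00162). Of 20 fibroblast and pericyte markers 18 rose and 1 fell, with a median of 0.79 (camera, adjusted p = 0.0015). With an estimated correlation these 3 lists gave adjusted p = 0.195, 0.263 and 0.195. Their medians after cyclic loess were 0.41, 0.37 and 0.38, and the fibroblast list passed there and after quantile normalization while the other 2 passed in neither. With an estimated correlation the fibroblast list passed in neither (adjusted p = 0.265 after quantile normalization and 0.235 after cyclic loess). The fibroblast list shares the collagen genes with the matrix list. Cd14, a leukocyte marker with a high control level of 10.78, fell by 1.70 (SE 0.10), with -1.04 after quantile normalization and -1.03 after cyclic loess. Fbln1 fell by 0.39 (SE 0.10), and by 0.60 after median centring. Another probe set of Fbln1 rose by 0.36, and the mean of its probe sets, at -0.02, did not pass. Ms4a1 and Laptm5 rose by 1.60 and 1.32 from control levels of 4.59 and 5.72, and Ms4a1 by 1.03 after cyclic loess.

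Among genes above the median level, the 12 with the largest rises also included Entpd4 at 2.44 (SE 0.10), Arpc3, a subunit gene of the actin-nucleating Arp2/3 complex, at 2.27 (SE 0.08), Slc24a4 at 2.21 (SE 0.11) and Get1 at 2.15 (SE 0.08). Ankrd1, a stretch-responsive gene, rose by 2.11 (SE 0.10), Sin3b by 2.07 (SE 0.10) and Pcdhb12 by 2.03 (SE 0.08). The 12 with the largest falls were led by Tcf7, a transcription factor gene of the Wnt pathway, at -4.31 (SE 0.10), and Zfp367 at -4.21 (SE 0.09). Depdc1 and Rflnb each fell by 3.94, the transcription factor gene Ets1 fell by 3.87 and Anxa8, an annexin gene, fell by 3.75. Ska1, which acts at the kinetochore, fell by 3.64, Top2a, a DNA topoisomerase gene, fell by 3.62 and Map2 fell by 3.59. The largest adjusted p was 3.46e-08 among the 12 rises and 3.71e-09 among the 12 falls (limma). Both groups of genes kept their direction in all 4 scalings. The probe sets of some of these genes differed. Sin3b had another probe set, at a higher control level of 8.56, that fell with a log2 fold change of -0.75, and the mean of its probe sets changed by 0.66. Map2 and Pcdhb12 each had another probe set whose change did not pass, at -0.17 and 0.18, and the means of their probe sets changed by -1.88 and 1.11. The mean of the probe sets of Slc24a4 changed by 1.16, and the other probe set of Get1 rose by 3.43.

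Of 41 lists, 12 passed the set test as deposited, 5 up and 7 down, and only the mitosis list passed with an estimated correlation. After quantile normalization 5 passed, 2 up and 3 down, and after cyclic loess 6, 3 up and 3 down. After either scaling 2 lists, those of mitosis and DNA replication, passed downward with an estimated correlation, and 0 passed upward. Against 10000 random lists of the same mean level, the medians of 10 lists lay outside the central 95%. Below it were the mitosis and DNA replication lists. The 8 above it were the mesenchymal (percentile 100), autophagy (99.9), cholesterol synthesis (99.9), collagen and matrix (99.8) and fatty acid oxidation (97.7) lists and the fibroblast (99.6), leukocyte (99.3) and proximal tubule (99.1) markers. Adjusted over the list alone, the counts of rising and falling members were those adjusted over all genes, except for 9 rising genes of cholesterol synthesis, 6 rising interferon genes, 1 rising and 20 falling proteasome genes, 18 falling ribosomal protein genes and 15 falling genes of the unfolded protein response.

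**Figure D3:**
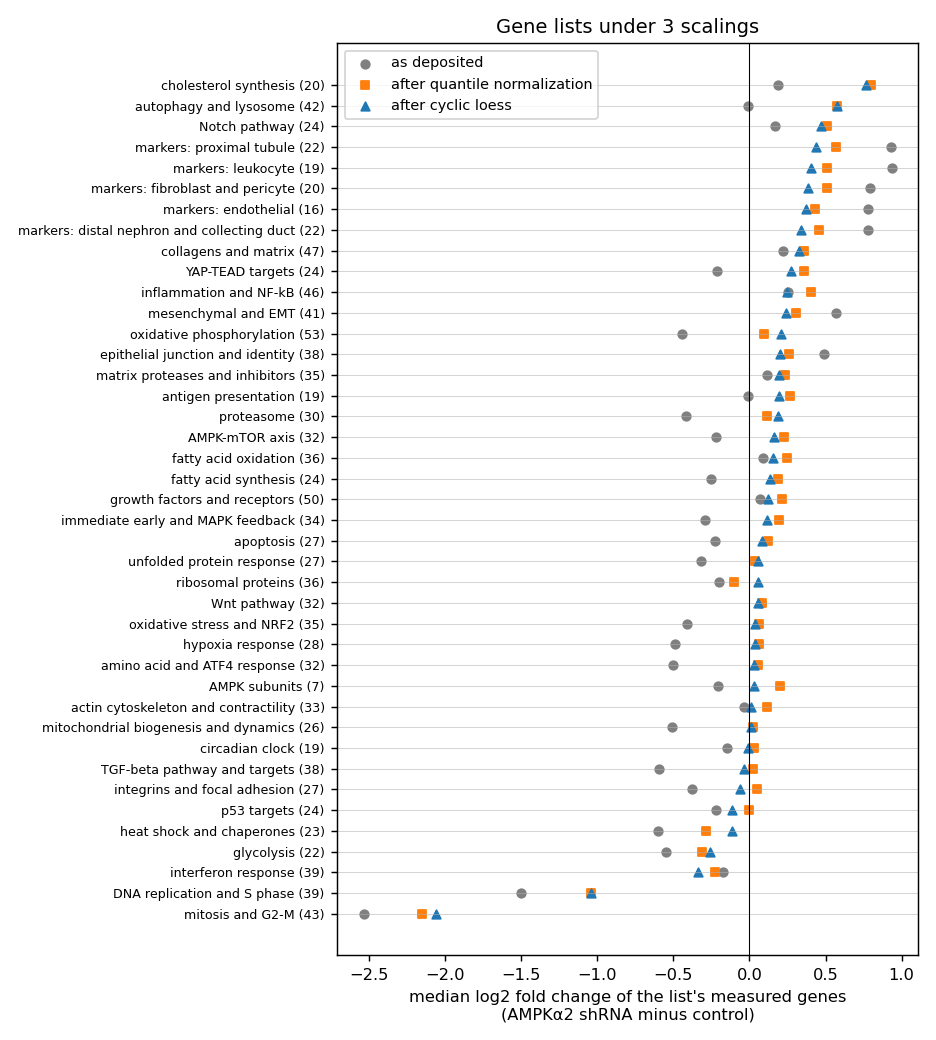
Median log2 fold change (AMPKα2 shRNA minus control) of the measured genes of each of 41 lists, with the number of genes in brackets, as deposited (grey circles), after quantile normalization (orange squares) and after cyclic loess (blue triangles). The mitosis list lay at -2.54, -2.15 and -2.06 and the DNA replication list at -1.50, -1.04 and -1.04, while the proteasome list went from -0.41 to 0.11 and 0.19.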

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

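The tests of the patterns in this part were chosen after the patterns had been seen, and cyclic loess was added after the data had been examined.

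Some control probe sets, which entered no gene test, were higher on every AMPKα2 shRNA array than on every control array. The 5S ribosomal RNA probe set was higher by 0.78, the B1 and B2 repeat probe sets by 0.33 and 0.53, and the middle hexokinase probe set by 0.25, while the 3′ and 5′ hexokinase probe sets had changes of -0.83 and -0.80. A pair of bacterial trpn probe sets, near the floor at control levels of 2.72 and 3.18, were higher by 0.23 and 0.50.

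The AMPKα2 shRNA arrays had a narrower range of values. In unscaled signal, a change in the cells' own transcripts alone would not lower spikes added at hybridisation in equal amounts. Nor would loss of 5′ ends from degraded RNA alone. Each of the 14 probe sets for bioB, bioC and bioD fell, with a change of -0.518 in the one that fell least. This argued against either cause alone only if the amounts were equal and the authors' normalization did not shift the spikes. Neither was tested. The normalization is not known, and the means per array were nearly equal, from 6.16 to 6.19, so a shift of the spikes by scaling stays possible. The SD of the bioB, bioC and bioD probe sets was 0.19 to 0.46 on the AMPKα2 shRNA arrays and 0.009 to 0.095 on the control arrays. Loss of 5′ ends as part of the cause stays open: the end probe sets of Actb and Gapdh lay near the top of the range, at control levels of 13.17 to 13.59, and the 3′ minus 5′ difference of hexokinase changed by -0.027, or up to 0.29 with 2 SE added. A change of measurement that also moves spikes may account for the falls at higher levels. There the bioB, bioC and bioD probe sets changed by -0.88 on average against -0.70 for genes of their level. They lay at control levels of 7.99 to 11.85, where genes fell, so they do not test the rises at low levels. The poly-A spikes dap, lys, phe and thr, at -1.21 against -0.14, did not follow the gene trend. Neither did the cre spikes, at 0.11 against -0.26. The poly-A probe sets fell even at levels where genes rose, as a lys probe set at a control level of 5.28 did, with -1.32 against 0.78. The trpn probe sets near the floor rose by 0.23 to 0.50, against 0.24 to 0.42 for genes of their level. The cre spikes lay near the top of the range, although 60.7% of genes with a control level above 12 passed as lower. The amount of spike added was not tested. How much of the gene changes arose in the cells stays open, because the range and the group coincide.

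The mitosis genes fell together. The level trend was argued against as the whole cause, since the list's median of -2.54 lay below the lowest median, -1.26, of 10000 random lists of the same mean level. Activation of p53 was not settled: the p53 target list's median was at percentile 52.6 of random lists of its level, and its members went both ways. In all 4 scalings 1 target was higher and 8 were lower. The p53 target Cdkn1a had a change of 0.12 that did not pass (limma, adjusted p = 0.204) and rises of 0.77 after both quantile normalization and cyclic loess, while Mdm2 fell by 0.46 (adjusted p = 0.000834) and its changes of 0.11 and 0.16 after these scalings did not pass. An effect of the hairpin on proliferation, through AMPKα2 or another transcript, is a hypothesis that stays open, together with any effect of the virus preparation or of cell density, which were not tested.

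Matrix, mesenchymal and actin genes were among the largest rises. Among 59 members of these lists with a control level above 8, 16 were higher, more than the highest of 10000 random sets matched on control level, 14. Their median change, -0.57, lay within the central 95% of such sets, -0.96 to -0.47. The level trend was thus argued against for the number that rose, but not for the median of the 59. Most of the 59, 38, were lower, and 13 of the 16 were higher in all 4 scalings. Among 56 members at or below that level, 39 were higher against a random median of 37, and their median change of 0.63 lay within the central 95% of random sets, 0.35 to 0.72, so the level trend may account for these. Over all levels, the median of the mesenchymal list, 0.57, lay just above the highest of 10000 random lists of its mean level, 0.55, and that of the collagen list at percentile 99.8. Random lists lack the correlation among a list's genes. The mesenchymal median was 0.31 after quantile normalization and 0.24 after cyclic loess, and the list passed in neither (camera, adjusted p = 0.331 and 0.237). Whether the trend was the whole cause was thus not settled for the mesenchymal list. The first summary tried, the median after cyclic loess of the 55 members that rose, was 1.03 with a lower quartile of 0.28, and was set aside because it ran on genes picked for rising. Admixed fibroblasts or pericytes stay open: the 13 markers in none of these lists had a median at percentile 95 of random lists of their level, and Dcn and Lum, abundant in fibroblasts, rose by 0.73 and 0.57, to 5.79 and 3.40. Fap, Thy1, Pdgfra and Pdgfrb rose as well, by 0.72 to 1.11, and after cyclic loess the changes of Dcn and Fap, 0.16 and 0.28, did not pass.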

How the results depend on the processing

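Cyclic loess was chosen after the data had been seen. Where a result changed below, the cause was not tested unless stated. The count of genes changed was 11573 to 12024 with 1 array left out, the 2-fold count 4032 to 4502, the probe sets 24030 to 25077, the lists 10 to 13 and the Prkaa2 change -0.27 to -0.14. Prkaa2 passed without AMPKα2 shRNA replicate 2 (-0.27), after median centring (-0.42), without the lowest 25% of genes (-0.21) and with the mean of probe sets (-0.21), and its adjusted p ranged from 0.00145 to 0.636 over all alternatives. Without the lowest 50%, where Prkaa2 itself is removed and fewer genes are tested, 6023 genes, 2406 at 2-fold, 13024 probe sets and 6 lists passed. Cyclic loess gave 2631 genes at 2-fold and 6 lists, quantile normalization 5 lists, camera with an estimated correlation 1 list and fry, which does not compare a list with other genes, 37.

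The values showed no pairing by replicate number: deviations of same-numbered arrays correlated at -0.02, 0.01 and -0.10. No label says whether the numbers mark shared cultures or days. With the replicate number as a block, 12039 genes, 4293 at 2-fold, 25274 probe sets and 11 lists passed.

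Signs turned in these cases. Quantile normalization gave Prkab1 0.50, Prkag1 0.47, Prkag2 0.12, Cdh1 -0.0314, Snai1 0.21, Tgfb1 0.0646 and Srebf2 0.20, and list medians of 0.20 (AMPK subunits), 0.23 (AMPK-mTOR axis), 0.12 (actin), 0.0241 (TGF-β) and 0.57 (autophagy). Cyclic loess gave Prkab1 0.47, Prkag1 0.42, Prkag2 0.0273, Cdh1 -0.11, Snai1 0.10 and Srebf2 0.17, and medians of 0.0273 (AMPK subunits), 0.16 (AMPK-mTOR axis), 0.0118 (actin) and 0.57 (autophagy). Median centring gave medians of -0.0286 (cholesterol) and -0.13 (fatty acid oxidation). Without the lowest 25% the medians were -0.0337 (inflammation) and -0.0795 (fatty acid oxidation), and without the lowest 50% they were -0.39 (collagens), -1.03 (epithelial), -0.36 (inflammation), 0.00498 (autophagy) and -0.43 (fatty acid oxidation). The mean of probe sets gave Prkag2 0.23, actin 0.0454 and autophagy 0.00817, and the most variable probe set gave Prkag2 0.85, Srebf2 0.52, Sesn1 -0.66 and actin 0.0707. Array weights gave actin 0.00908 and autophagy 0.0246. With 1 array left out, the actin median ranged from -0.0835 to 0.0469 and the autophagy median from -0.0306 to 0.0411, both highest without AMPKα2 shRNA replicate 3, and Snai1 ranged from -0.122 to 0.00664, highest without control replicate 3. Of 87 named genes other than Prkaa2, 78 kept direction and side of the threshold after quantile normalization and 75 after cyclic loess.

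Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split gave 12095 genes, 4293 at 2-fold and 25419 probe sets, against at most 0 in the others, so 1 split reached each count. For the lists the real split gave 12 and the highest other 14, and 6 of the 10 splits gave at least 12. Each other split puts arrays of both groups on each side. Part of the group difference thus stays in its comparison, and the rest widens the spread within its sides. Neither the 0 genes nor the numbers of lists in the other splits therefore show what chance alone gives.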

Other observations

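Nephron segment markers, at low levels in these cells, were higher on the AMPKα2 shRNA arrays as the markers of other cell types were. Of 22 proximal tubule markers 19 rose and 2 fell, with a median log2 fold change of 0.93 (camera, adjusted p = 0.00162, and adjusted p = 0.594 with an estimated correlation). Of 22 distal nephron and collecting duct markers 19 rose and 2 fell, with a median of 0.78 (camera, adjusted p = 0.00294, and adjusted p = 0.197 with an estimated correlation). Neither list passed after quantile normalization or cyclic loess.

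Apart from the mitosis and DNA replication lists, 5 lists passed the set test downward as deposited. Of 53 oxidative phosphorylation genes 6 rose and 31 fell, with a median of -0.44, and of 30 proteasome genes 2 rose and 22 fell, with a median of -0.41 (camera, adjusted p = 0.0187 for both). Of 23 heat shock and chaperone genes 2 rose and 18 fell, with a median of -0.60 (camera, adjusted p = 0.0086). Of 26 genes of mitochondrial biogenesis 5 rose and 19 fell, with a median of -0.51 (camera, adjusted p = 0.0478), and of 32 genes of the amino acid response 5 rose and 19 fell, with a median of -0.50 (camera, adjusted p = 0.0428). With an estimated correlation these 5 lists gave adjusted p = 0.801 for oxidative phosphorylation and 0.793 for each of the others. After quantile normalization none of the 5 passed, and the medians of all but the heat shock list turned above 0. Against random lists of the same mean level, the medians as deposited lay within the central 95%, at percentiles of 57.3 for oxidative phosphorylation, 56.9 for the proteasome, 9.37 for heat shock, 36.1 for mitochondrial biogenesis and 44.4 for the amino acid response.

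The other lists did not pass the set test as deposited. The medians were -0.55 for glycolysis (5 of 22 genes rose and 12 fell), -0.49 for the hypoxia response (9 of 28 rose, 19 fell), -0.41 for oxidative stress (9 of 35 rose, 21 fell) and -0.38 for integrins (5 of 27 rose, 15 fell). They were -0.32 for the unfolded protein response (5 of 27 rose, 16 fell), -0.29 for immediate early genes (11 of 34 rose, 19 fell), -0.26 for fatty acid synthesis (8 of 24 rose, 12 fell) and -0.23 for apoptosis (8 of 27 rose, 15 fell). For YAP-TEAD targets the median was -0.21 (9 of 24 rose, 11 fell), for ribosomal proteins -0.20 (1 of 36 rose, 20 fell), for the circadian clock -0.15 (8 of 19 rose, 8 fell) and for antigen presentation -0.01 (7 of 19 rose, 7 fell). For growth factors it was 0.07 (22 of 50 rose, 21 fell), for the Wnt pathway 0.08 (14 of 32 rose, 12 fell), for matrix proteases 0.11 (15 of 35 rose, 12 fell) and for the Notch pathway 0.17 (11 of 24 rose, 7 fell). After quantile normalization the negative medians turned above 0 except for glycolysis and ribosomal proteins.

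The AMPKα1 gene Prkaa1 fell by 2.34 while the targeted Prkaa2 had a change of -0.21 that did not pass. The hairpin's sequence was not used here, so whether it targets Prkaa1 was not checked. The values on the single arrays did not overlap for either gene, nor did they for 87.1% of all genes.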
